A study of Mus musculus with 6 samples.

How the data were processed

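Gene expression was measured with 1-colour Affymetrix arrays on total RNA of primary mouse keratinocytes, 1 pool of cells per genotype and litter. Per the labels, RNA was extracted with Trizol, and biotin-labelled targets were made with an in vitro transcription labelling kit. The deposited table holds 1 linear intensity per probe set and array. How the authors corrected background, summarised probes and scaled the arrays is not given in the sources used here. Per the labels, 3 arrays are controls and 3 are Gpx4 knockouts, each group has litters A, B and C, and the arrays are described as biological replicates.

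The deposited intensities ran from 0 to 9550.8 and were not on a log scale. Their mean, trimmed of 2% at each end, differed by up to 1.57-fold between arrays, and in litter C the control was 1.56-fold brighter than the knockout, so the table had not been brought to a common level. The design set before the data were examined tested the intensities scaled as deposited, with quantile normalization as an alternative. Because unnormalized 1-colour arrays need normalization between arrays, quantile normalization was made the reported setting once the intensities were seen and before the fits were compared, and the text says where the deposited scaling ends a call, turns a direction or moves a list's median by over 1.5 times. The tests, the threshold, the gene lists, the rule for naming genes and the other alternatives were also fixed before the data were examined, except where an alternative is described as added.

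The 64 control probe sets were left out, which left 45037 probe sets. Intensities were quantile-normalized between the 6 arrays and tested as log2(intensity + 16) in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with an intensity trend. Litter was a block, as the submitters' design compares knockout and control pools of one litter. The labels name the litter of each array, and this pairs the arrays. The residuals of same-litter arrays about their group means correlated with r = 0.17, 0.047 and 0.21 in litters A, B and C. Two-sided p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p given for single genes come from limma. Folds are on the log2(intensity + 16) scale, and levels are given without the added 16.

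Gene symbols came from the platform annotation of 2016 and were compared with a RefSeq gene table of GRCm38.p6, which also gave membership of the X and Y chromosomes. Of the tested probe sets 34945 had 1 gene, 932 had several and 9160 were not listed, and those with several or none were counted and not named. For a gene with several probe sets the one with the highest mean over all 6 arrays was used, and no gene passed the threshold in both directions on different probe sets.

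The lists held 559 entries in 24 groups: keratinocyte states, pathways around lipid peroxides and stress, markers of other skin cells and sex-linked genes. Of these, 39 were not matched and are not reported here. A few genes stand in 2 lists, such as Chac1. Lists were tested with camera with a preset correlation of 0.01 between genes, with camera with an estimated correlation, and with fry. With the preset correlation 14 of the 24 lists passed, 8 up and 6 down, and with an estimated correlation 0 passed (1 at an unadjusted p under 0.05). Camera with an estimated correlation takes its degrees of freedom from the residuals of these 6 arrays. A failure there therefore does not by itself show that correlation between genes removes a shift. The melanocyte list had an estimated correlation of -0.0354, under the preset 0.01, and its unadjusted camera p still went from 2.63e-10 to 0.0218. The estimate was highest in the interferon-stimulated (0.557), immediate-early (0.536), fibroblast (0.527) and unfolded protein response (0.495) lists. If their genes vary together to that degree, their camera p with the preset correlation is too small. Their unadjusted fry p was 0.111, 0.187, 0.231 and 0.246. By fry 2 passed for a shift in one direction and 14 for change in either direction. Fry does not compare a list with other genes. Genes were named by a rule: Gpx4, the 12 highest and 12 lowest log2 changes among probe sets with 1 gene that passed with the same sign in all 3 litters, up to 4 members of each list with the smallest unadjusted p, and Ptgs2. For the 12 highest and lowest, a gene counted where the brightest of all its probe sets passed. With the brightest passing probe set instead, Cxcl1, Tgfbi and Syt4 would replace Actg2, Sostdc1 and Nfatc1.

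The steps were tested on simulated arrays drawn from the means and spread of these data, with 200 of 45037 probe sets changed in each of 10 simulations. The changed probe sets were drawn from those brighter than the median, so the shares found do not hold for dim probe sets. Of simulated 2-fold changes 14.3% were found and of 4-fold changes 69.2%, and 1.07% of all calls were false. A list made only of probe sets raised 2-fold was found in 10 of 10 simulations, and 3.25% of 2000 unshifted lists had an unadjusted camera p under 0.05. The real lists had smaller median changes or members that moved both ways, so the first result does not say how often such lists are found. The simulated probe sets had independent errors and the lists were drawn at random. The simulation therefore does not check the list test for genes that vary together. In these data the estimated correlation reached 0.557 in the interferon-stimulated list.

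The alternatives were a fit without the litter block, the deposited scaling, a shift of each array to the same median, leaving out the 40% dimmest probe sets, eBayes without trend or robust, a pseudocount of 1 or 64, other thresholds, a plain paired test per probe set, 1 probe set per gene or the mean over a gene's probe sets, and leaving out each litter or array. Scaling each array to the same trimmed mean, and leaving out the genes of X and Y, were added after seeing the data. Signal over background limits dim genes, since 45.4% to 50% of probe sets of an array were under the added 16. The ratio of 3' to 5' control probe sets was 1.18 to 1.29 for actin and 0.675 to 0.74 for Gapdh over the 6 arrays. Plots were drawn with matplotlib 3.10.9.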

Results

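Messenger RNA was profiled in primary keratinocytes, the epithelial cells of the epidermis, cultured from the skin of newborn mice on a mixed C57BL6 and FVB background. Gpx4, a selenium-containing enzyme that reduces lipid hydroperoxides in membranes, had been removed by a cre recombinase driven by the keratin 14 promoter, which is active in basal keratinocytes. Pools of knockout and control keratinocytes were compared within each of 3 litters, A, B and C, which gave 3 control arrays and 3 knockout arrays. The medium held 100 nM sodium selenite, the selenium source for selenoprotein synthesis. Each array measured 45101 probe sets, and the number of arrays limits the precision of every value. The median intensity of an array lay between 15.9 and 20.4, and 45.4% to 50% of the probe sets of an array were under 16. The mean intensity trimmed at both ends was 73.2, 90 and 114.8 in the controls of litters A, B and C and 74.3, 92.4 and 73.8 in the knockouts. Levels below are quantile-normalized intensities as mean ± SD over 3 arrays, and log2 changes are knockout minus control ± SE from limma with litter as a block, on log2(intensity + 16), a scale that understates the change of dim genes.

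The targeted gene was examined first. Gpx4 fell in the knockout of all 3 litters: the brighter of its 2 probe sets had an intensity of 527.7 ± 28.5 in controls and 229.3 ± 26.5 in knockouts. The log2 change was -1.15 ± 0.091, or 2.22-fold lower (limma adjusted p = 0.0208), with -1.17, -1.04 and -1.25 in litters A, B and C. The other Gpx4 probe set gave 382.7 ± 90.4 and 136.1 ± 42.2, a log2 change of -1.40 ± 0.21 that did not pass (adjusted p = 0.063). The labels do not say which part of the gene was deleted, so signal left in the knockout arrays does not measure undeleted cells. With the intensities scaled as deposited the brighter probe set had a log2 change of -1.34 and did not pass (adjusted p = 0.122), and without litter A or litter B it did not pass either (adjusted p = 0.15 and 0.276).

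Gsta4, Fosl1, Ereg and Ptgs2 had the highest log2 changes of the genes that rose in the knockout of all 3 litters. Gsta4, a glutathione transferase that acts on lipid aldehydes, rose from 27.4 ± 2.23 to 277.1 ± 69.9 (log2 change 2.73 ± 0.16, adjusted p = 0.00931). Fosl1, a subunit of the AP-1 transcription factor, rose from 56.8 ± 16.1 to 419.1 ± 159.6 (2.53 ± 0.29, adjusted p = 0.0379), and Ereg, the EGF receptor ligand epiregulin, from 34.8 ± 9.04 to 243.4 ± 62.3 (2.34 ± 0.22, adjusted p = 0.0314). Ptgs2, the inducible cyclooxygenase COX-2, rose from 697.6 ± 271.8 to 3395 ± 496.5 (2.31 ± 0.24, adjusted p = 0.0345), with log2 changes of 2.66, 2.78 and 1.5 in litters A, B and C. The other 8 of the 12 highest genes were Bcl2l15, a Bcl-2 family member (2.22 ± 0.18), Phlda1 (2.13 ± 0.27), Mal (2.06 ± 0.14), the atrial myosin light chain Myl7 (1.86 ± 0.11), the peptide hormone precursor Adm (1.65 ± 0.20), Ripor2 (1.6 ± 0.13), the kinase anchor Akap12 (1.57 ± 0.18) and the smooth muscle actin Actg2 (1.5 ± 0.18). Their adjusted p lay between 0.00931 and 0.0448. As deposited, Gsta4 and Mal passed and the other 10 did not, among them Fosl1 (2.33, adjusted p = 0.0719), Ereg (2.14, 0.0569) and Ptgs2 (2.15, 0.0782). Without the litter block Mal, Myl7 and Adm did not pass (adjusted p = 0.167, 0.0659 and 0.0529).

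Among the genes that fell, 3 of the 12 lowest lie on the Y chromosome. Eif2s3y went from 173.1 ± 15.7 in controls to 2.82 ± 2 in knockouts (log2 change -3.33 ± 0.15, adjusted p = 0.00668), and Kdm5d and Uty had log2 changes of -2.01 ± 0.15 and -1.95 ± 0.17. Of the others, Gas1, a growth arrest gene that also encodes a hedgehog co-receptor, fell from 734 ± 359.2 to 107.7 ± 0.912 (-2.46 ± 0.28, adjusted p = 0.0377), and the follicular keratin Krt79 from 393.7 ± 23.7 to 87.9 ± 36.8 (-2.05 ± 0.23, adjusted p = 0.0373). Sostdc1, a secreted BMP and Wnt antagonist, fell from 2903.1 ± 1569.9 to 866.8 ± 325.3 (-1.59 ± 0.19, adjusted p = 0.0398), and Nfatc1, a transcription factor of hair follicle stem cells, from 260.1 ± 26.7 to 84.1 ± 20.3 (-1.48 ± 0.13, adjusted p = 0.0227). Sbspon (-1.84 ± 0.24), the proteoglycan Cspg4 (-1.80 ± 0.23), Nrep (-1.68 ± 0.14), the adhesion receptor Adgra3 (-1.63 ± 0.18) and the receptor kinase Mertk (-1.6 ± 0.18) completed the 12, with adjusted p between 0.0214 and 0.0489. As deposited, Krt79 (-2.22, adjusted p = 0.0622) and Nfatc1 (-1.66, 0.0719) did not pass. Without the litter block Sbspon, Cspg4, Nrep, Mertk and Sostdc1 did not pass (adjusted p between 0.0539 and 0.221).

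**Figure D1:**
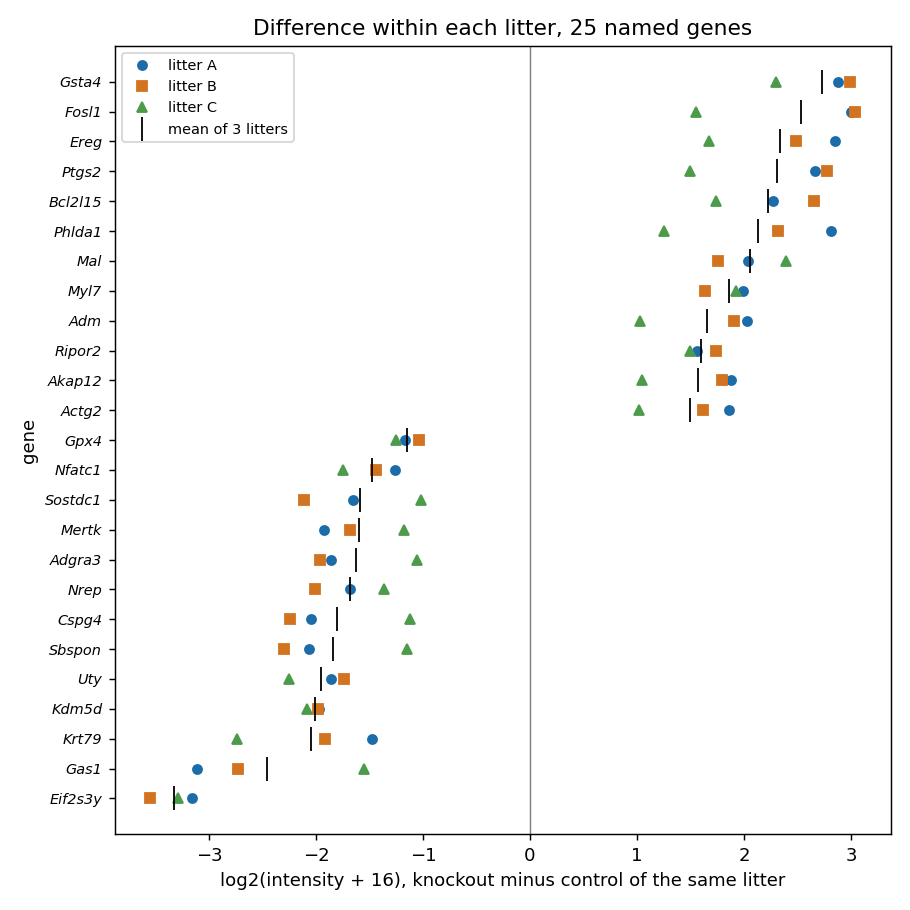
Knockout minus control of log2(intensity + 16) within litter A (circle), B (square) and C (triangle) for Gpx4 and the 12 highest and 12 lowest genes, with a bar at the mean of the 3 litters. The 12 highest and 12 lowest genes were chosen to have the same sign in all 3 litters, so their points lie on the side of 0 of their mean by that rule. Gpx4, named without it, lies below 0 in each litter. For Ptgs2 litter C (1.5) lies below litters A (2.66) and B (2.78).

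Over all 45037 probe sets tested, 189 passed an adjusted p of 0.05, 71 higher and 118 lower in the knockout. They name 53 higher and 83 lower genes and 26 are unnamed. Of the 189, 48 were higher and 74 lower by at least 2-fold, and all 189 had the same sign in the 3 litters. The test pairs the arrays by litter and favours probe sets whose 3 differences are alike, so the shared sign is no separate support. An unadjusted p under 0.05 was reached by 6593 probe sets, against 2252 by chance. With the intensities scaled as deposited 35 probe sets passed, 3 higher and 32 lower, and the share of higher calls went from 37.6% to 8.57%. Without litter A 3 passed, without litter B limma gave 0 (3702 at an unadjusted p under 0.05), and without litter C 2761 passed, 1349 higher and 1412 lower, with all 189 among them. Of the 24 highest and lowest genes 1 passed without litter A, 0 without litter B and 24 without litter C.

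The knockout removes an enzyme of lipid peroxide metabolism, so the genes of prostaglandin and leukotriene synthesis were examined as a list. Beside Ptgs2, the prostaglandin E synthase Ptges rose from 93 ± 10.1 to 197.3 ± 17.6 (log2 change 0.97 ± 0.11, adjusted p = 0.0373), with 1.08, 0.90 and 0.93 in litters A, B and C. Pla2g4a, the cytosolic phospholipase A2 that frees arachidonic acid, had a log2 change of 0.44 ± 0.10 and the secreted phospholipase Pla2g2f one of -1.40 ± 0.26. Neither passed over all genes (adjusted p = 0.134 and 0.0887), and both passed when adjusted over the list alone (0.0301 and 0.0133). Of the 30 measured members 2 rose over all genes and none fell, and adjusted over the list alone 3 rose and 2 fell. The list as a whole did not shift (camera adjusted p = 0.854), and its median of -0.06 and mean of 0.02 differ in sign. As deposited, Ptges did not pass (0.77, adjusted p = 0.324).

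**Figure D2:**
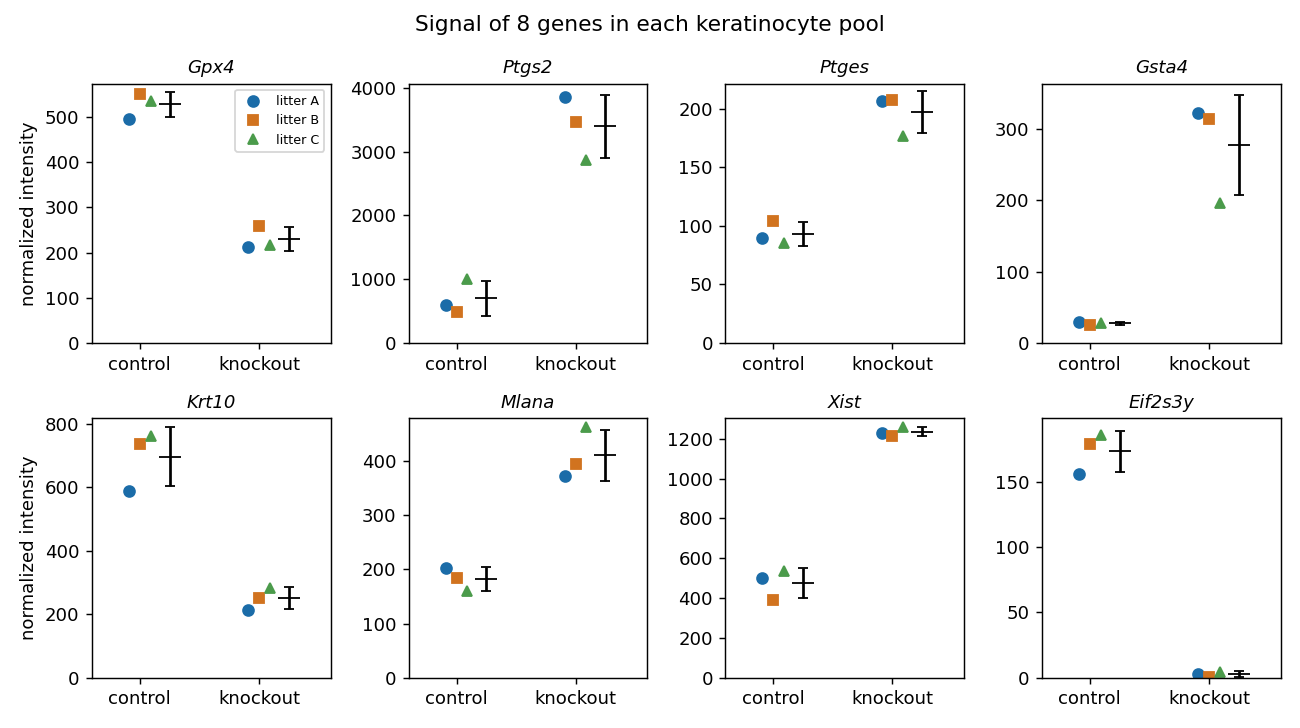
Quantile-normalized intensity of 8 genes in the control and knockout pools of litters A (circle), B (square) and C (triangle), each axis starting at 0, with the mean and SD of 3 arrays in black. In each of the 8 genes the 3 knockout points lie wholly above (Ptgs2, Ptges, Gsta4, Mlana, Xist) or wholly below (Gpx4, Krt10, Eif2s3y) the 3 control points. All 8 are genes that passed the threshold, so this separation is no separate support.

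Cytokine genes changed in both directions. Tslp, an epithelial cytokine of allergic inflammation, fell from 3714.8 ± 80.1 to 1895.5 ± 192.9 (-0.97 ± 0.083, adjusted p = 0.0219), and Il18, an interleukin 1 family cytokine, from 159.6 ± 9.77 to 48.6 ± 8.47 (-1.45 ± 0.14, adjusted p = 0.0314). Csf1, the macrophage colony-stimulating factor, rose from 32.6 ± 8.25 to 108.8 ± 18.3 (1.36 ± 0.13, adjusted p = 0.0314). The neutrophil chemokine Cxcl1 had a log2 change of 2.25 ± 0.30 on its brighter probe set (adjusted p = 0.0507), and another of its probe sets passed at 2.12 ± 0.28 (adjusted p = 0.0457; 0.1 as deposited). Of 33 inflammatory genes 1 rose and 2 fell over all genes, and adjusted over the list alone 6 rose and 4 fell. The list was shifted up (median 0.23, camera adjusted p = 0.0473), with an adjusted p = 0.465 with an estimated correlation. The shift of the list did not pass without the litter block (adjusted p = 0.0758), without litter B (median 0.111, 0.196), with the mean of each gene's probe sets (0.0645) or with a pseudocount of 64 (median 0.12, 0.0531). Its median was 0.127 with each array shifted to the same median and 0.07 as deposited, and Tslp (-1.13, adjusted p = 0.172), Il18 (-1.62, 0.0719) and Csf1 (1.18, 0.129) did not pass.

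Immediate-early and stress-associated keratinocyte genes were higher as lists with the preset correlation (camera adjusted p = 9.47e-06 and 0.000131) and did not pass with an estimated one (adjusted p = 0.555 and 0.465). Ccn1, an early growth factor response gene, rose from 483.6 ± 215.5 to 1001 ± 222.1 (1.09 ± 0.12, adjusted p = 0.0372), beside Fosl1. Myc (0.76 ± 0.13, adjusted p = 0.076) and Ier3 (0.84 ± 0.15, adjusted p = 0.0818) passed adjusted over the list alone (both 0.00581). Of 24 immediate-early genes 2 rose over all genes and 9 adjusted over the list alone, and none fell by either count (median 0.61). Their median was 0.99 in litter A, 0.84 in litter B and -0.10 in litter C, whose control array lay 0.811 above the other controls by the median of these genes. Without litter C 16 of the 24 rose and 1 fell over all genes (median 0.94). With a litter or an array left out the median lay between 0.424 and 0.94, and as deposited it was 0.437. Ccn1 did not pass as deposited (0.91, adjusted p = 0.336) or without the litter block (0.16). Of 16 stress-associated genes Ereg rose over all genes, and adjusted over the list alone 6 rose and 1 fell (median 0.29). The urokinase receptor Plaur had a log2 change of 1.99 ± 0.29 (adjusted p = 0.0607), the EGF receptor ligand Hbegf 1.64 ± 0.29 (adjusted p = 0.0824) and Serpinb2 0.58 ± 0.09 (adjusted p = 0.0677). As deposited the median of the stress-associated list was 0.15.

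Genes of epidermal layers were measured to ask whether the state of the keratinocytes differed. Krt10, a keratin of the suprabasal layers, fell from 696.1 ± 92.6 to 250.1 ± 34.4 (-1.42 ± 0.084, adjusted p = 0.00931), with -1.39, -1.49 and -1.38 in litters A, B and C. Its partner Krt1 (-1.21 ± 0.22, adjusted p = 0.0835), the desmosomal cadherin Dsc1 (-1.07 ± 0.19, adjusted p = 0.0804) and Calm4 (-1.12 ± 0.22, adjusted p = 0.0973) passed adjusted over the list alone. With a litter or an array left out Calm4 lay between -1.54 and -0.51. Of 38 differentiation genes 1 fell over all genes, and adjusted over the list alone 4 rose and 9 fell. The list did not shift (median -0.09, camera adjusted p = 0.153). Without litter C its median was 0.08 (camera adjusted p = 0.624), and it was shifted down without litter A (-0.25, 0.00547) or litter B (-0.13, 0.0137). Without litter C 7 of the 38 rose over all genes and 9 fell. Tgm1 (1.48 ± 0.14), Cnfn (1.39 ± 0.12) and Sprr2h (1.03 ± 0.073) were among those that rose. It also passed as deposited (-0.23, camera adjusted p = 0.0495) and with each array shifted to the same median (-0.17, 0.00962), whereas Krt10 did not pass as deposited (-1.61, adjusted p = 0.0622).

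Basal keratinocyte genes were lower as a list (19 measured, median -0.16, camera adjusted p = 0.0254; adjusted p = 0.612 with an estimated correlation), and none passed over all genes. Adjusted over the list alone, Trp63, the transcription factor of stratified epithelia (-0.43 ± 0.076), and the stem cell keratin Krt15 (-2.49 ± 0.65) fell, and the integrin Itga3 (0.78 ± 0.19) rose. The plakin Dst had a log2 change of -0.25 ± 0.073 and did not pass either way. Krt15 had log2 changes of -3.39, -3.84 and -0.25 in litters A, B and C. The median of the list was -0.30, -0.23 and 0.06 in these litters. Without litter C 1 of the 19 rose and 6 fell over all genes (camera adjusted p = 0.000112), with a median of -0.273. The list did not pass without litter A (median -0.0612, 0.221), without litter B (0.112) or with the mean of each gene's probe sets (-0.0636, 0.118). With 1 array left out and no block it passed only without an array of litter C. As deposited its median was -0.34.

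Hair follicle genes were lower as a list (37 measured, median -0.11, camera adjusted p = 0.0434; adjusted p = 0.465 with an estimated correlation). Beside the fall of Krt79, Fst, which encodes the activin-binding protein follistatin, rose from 1360.8 ± 174.8 to 3596.4 ± 190.5 (1.40 ± 0.079, adjusted p = 0.00931). The transcription factors Sox9 (-0.66 ± 0.12, adjusted p = 0.0824) and Lhx2 (-0.73 ± 0.14, adjusted p = 0.0921) passed adjusted over the list alone. Over all genes 1 rose and 1 fell, and adjusted over the list alone 2 rose and 9 fell. The shift of the list did not pass without the litter block (adjusted p = 0.0528), as deposited (0.0518, median -0.20), without litter A (0.115) or with the mean of each gene's probe sets (0.0532). Its median was -0.169 without litter C, -0.293 without the 40% dimmest probe sets, -0.373 with a pseudocount of 1 and -0.0566 with 64. As deposited, Fst did not pass (1.24, adjusted p = 0.148).

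Selenoproteins, the family to which Gpx4 belongs, were lower as a list (23 measured, median -0.19, camera adjusted p = 0.0195; adjusted p = 0.465 with an estimated correlation). Gpx4 was the 1 member that fell over all genes, and adjusted over the list alone 6 fell and 1 rose. The fall of Gpx4 is part of the design, and the list test and these counts include it. The list was not tested without Gpx4. The shift of the list did not pass without litter A (median -0.113, camera adjusted p = 0.171), nor without the litter block when the control of litter C or the knockout of litter A was left out (0.0519 and 0.106). Its median was -0.363 with a pseudocount of 1, -0.114 with 64 and -0.0985 with the mean of each gene's probe sets. The plasma selenium carrier Selenop had a log2 change of -0.91 ± 0.13 (adjusted p = 0.0542), the methionine sulfoxide reductase Msrb1 one of -0.62 ± 0.13 (adjusted p = 0.113) and the thioredoxin reductase Txnrd1 one of 0.98 ± 0.18 (adjusted p = 0.0895). Antioxidant and NRF2-regulated genes did not shift as a list (32 measured, median 0.08, camera adjusted p = 0.399), and their median was -0.08 as deposited, -0.02 with each array shifted to the same median and -0.02 without litter C. Gsta4 was the 1 member that rose over all genes, and adjusted over the list alone 3 rose and 5 fell. Among them Ugdh (-0.75 ± 0.10) and the glutathione transferase Gstm2 (-0.87 ± 0.17) were lower and the glutathione reductase Gsr (0.47 ± 0.10) was higher, with adjusted p over all genes of 0.0536, 0.105 and 0.126. Gsr lay between 0.3 and 0.61 with a litter or an array left out.

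Genes of ferroptosis, the iron-dependent cell death that Gpx4 opposes, of iron handling and of polyunsaturated lipids did not shift as a list (22 measured, camera adjusted p = 0.854), and none passed over all genes. The median of 0.04 and the mean of -0.02 differ in sign, and as deposited the median was -0.16. Adjusted over the list alone, the transferrin receptor Tfrc (0.79 ± 0.11) and the glutathione-degrading Chac1 (0.52 ± 0.12) rose, and the desaturase Fads2 (-0.94 ± 0.18) and the iron exporter Slc40a1 (-1.11 ± 0.27) fell. Their adjusted p over all genes was 0.0516, 0.136, 0.097 and 0.148. With a litter or an array left out Slc40a1 lay between -1.43 and -0.69, with -0.69 without litter C.

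Cholesterol synthesis genes were shifted down as a list with the preset correlation (20 measured, median -0.28, camera adjusted p = 2.32e-05) and did not pass with an estimated one (adjusted p = 0.465). Of the 20, 4 had a positive log2 change and 16 a negative one. Fdps, farnesyl diphosphate synthase, fell from 1143.2 ± 146.1 to 619.9 ± 23 (-0.86 ± 0.098, adjusted p = 0.0379), and Fdft1, squalene synthase, from 569.7 ± 21.5 to 345.6 ± 28.9 (-0.70 ± 0.09, adjusted p = 0.0455). Idi1 had a log2 change of -0.70 ± 0.10 (adjusted p = 0.0622). Hmgcs1 had one of -0.43 ± 0.078 on its brighter probe set (adjusted p = 0.0834), and another of its probe sets passed at -0.64 ± 0.081 (adjusted p = 0.0451; 0.309 as deposited). Over all genes 2 fell, and adjusted over the list alone 10 fell and 1 rose. The median was -0.39, -0.36 and -0.20 in litters A, B and C. As deposited the median was -0.47, and Fdps (-1.04, adjusted p = 0.172) and Fdft1 (-0.89, 0.258) did not pass.

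Cell cycle genes were lower as a list by a small amount (39 measured, median -0.10, camera adjusted p = 0.00363; adjusted p = 0.465 with an estimated correlation). None passed over all genes, and adjusted over the list alone 4 fell: the mitotic cyclin Ccnb2 (-0.62 ± 0.088), Cdc20 (-0.44 ± 0.082), the proliferation antigen gene Mki67 (-0.41 ± 0.086) and the kinesin Kif20a (-0.47 ± 0.10). Without litter C the list did not pass (camera adjusted p = 0.078), nor without the block and the control of litter C (median -0.0425, 0.378). The median was -0.178 without litter B, -0.212 with each array shifted to the same median and -0.27 as deposited.

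The p53-regulated genes were higher as a list (24 measured, median 0.22, camera adjusted p = 0.0217; adjusted p = 0.553 with an estimated correlation). None passed over all genes, and adjusted over the list alone 6 rose and 2 fell. The nuclease Aen (0.73 ± 0.13), Ccng1 (0.32 ± 0.079) and the p53 ubiquitin ligase Mdm2 (0.56 ± 0.15) were higher, and Trp53i11 (-0.51 ± 0.13) was lower. With a litter or an array left out Ccng1 lay between 0.21 and 0.47 and Trp53i11 between -0.75 and -0.33. As deposited, and with each array shifted to the same median, the list did not pass (medians 0.04 and 0.10, camera adjusted p = 0.272 and 0.318), nor did it without litter A (median 0.111, 0.22) or with the mean of each gene's probe sets (0.0635).

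Unfolded protein response and ATF4-regulated genes were higher as a list (30 measured, median 0.24, camera adjusted p = 2.32e-05; adjusted p = 0.575 with an estimated correlation). None passed over all genes, and adjusted over the list alone the amino acid transporter Slc7a5 (0.47 ± 0.10), the serine synthesis enzyme Phgdh (0.57 ± 0.13) and Chac1 rose and none fell. The pseudokinase Trib3 had a log2 change of 0.86 ± 0.22 and did not pass. Without litter C 11 of the 30 rose over all genes and none fell, and as deposited the median was 0.08. With each array shifted to the same median it was 0.144 (camera adjusted p = 0.0383) and without litter A 0.141 (0.0123). Heat shock genes did not shift (15 measured, median 0.10, camera adjusted p = 0.99; median -0.09 as deposited). None passed over all genes, and adjusted over the list alone 2 rose, the chaperones Hsp90aa1 (0.60 ± 0.11) and Hspd1 (0.39 ± 0.079), and 3 fell, among them Dnajb1 (-0.79 ± 0.13) and Hspa4l (-0.69 ± 0.10).

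Interferon-stimulated genes were higher as a list (23 measured, median 0.745, camera adjusted p = 4.43e-09; adjusted p = 0.526 with an estimated correlation). None passed over all genes, and adjusted over the list alone 13 rose and none fell. The regulator Irf7 had a log2 change of 1.40 ± 0.19 (adjusted p = 0.0507), the GTPase Gbp3 one of 1.23 ± 0.20 (0.0702), Ifit3 one of 1.46 ± 0.26 (0.082) and the antiviral membrane protein Bst2 one of 1.53 ± 0.29 (0.0899). With a litter or an array left out Gbp3 lay between 0.72 and 1.72 and Ifit3 between 0.96 and 2.07. The spread within groups was wide, as in Irf7 with 114.2 ± 99.6 in controls and 309.3 ± 188.6 in knockouts. The median was 0.36, 1.22 and 0.60 in litters A, B and C. Without litter B the median of the list fell to 0.449 (camera adjusted p = 8.68e-08), and with a pseudocount of 64 to 0.439. Without the litter block and the knockout array of litter C it was 0.367 and the list did not pass (0.117).

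**Figure D3:**
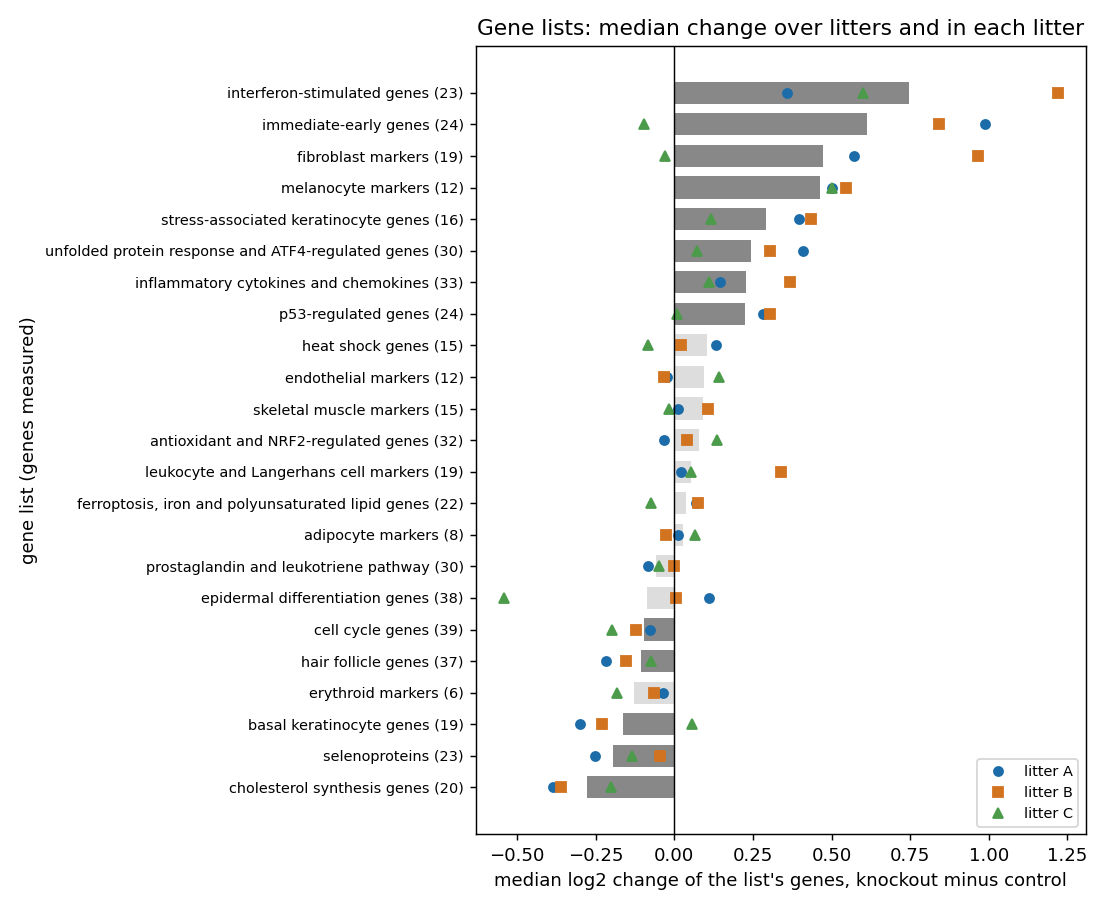
Median log2 change, knockout minus control, of 23 gene lists over the 3 litters (bars; dark grey where the camera adjusted p with the preset correlation passed 0.05, light grey where not) and in litters A (circle), B (square) and C (triangle). Melanocyte markers lie at 0.50, 0.55 and 0.50 in the litters, whereas immediate-early genes lie at 0.99, 0.84 and -0.10.

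Markers of other cells that a skin preparation can hold were measured in the same arrays. Of the melanocyte genes Tyrp1, a melanin synthesis enzyme, rose from 1117.9 ± 91.7 to 1817.6 ± 167 (0.69 ± 0.079, adjusted p = 0.0379), Mlana from 182.6 ± 22 to 411.2 ± 47.1 (1.11 ± 0.14, adjusted p = 0.0428) and Oca2 from 54.1 ± 3.25 to 127.7 ± 8.77 (1.03 ± 0.12, adjusted p = 0.0377). Pmel had a log2 change of 0.47 ± 0.079 (adjusted p = 0.0774). All 12 melanocyte genes had a positive log2 change, 3 rose over all genes and 9 adjusted over the list alone (median 0.46, camera adjusted p = 4.43e-09; adjusted p = 0.465 with an estimated correlation; fry adjusted p = 0.0148). As deposited the median was 0.31 and Tyrp1 (0.54, adjusted p = 0.539), Mlana (0.92, 0.209) and Oca2 (0.84, 0.243) did not pass.

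Fibroblast genes were higher as a list (19 measured, median 0.47, camera adjusted p = 0.00255; adjusted p = 0.575 with an estimated correlation). The collagen Col5a2 rose from 154.5 ± 82.4 to 354.9 ± 131 (1.16 ± 0.14, adjusted p = 0.0394) and the matrix protein Sparc from 301.4 ± 76.1 to 546.9 ± 176.8 (0.80 ± 0.11, adjusted p = 0.0488). Vimentin, Vim, had a log2 change of 1.58 ± 0.25 (adjusted p = 0.068) and fibronectin, Fn1, one of -0.61 ± 0.087 (adjusted p = 0.0556). Adjusted over the list alone 9 rose and 2 fell, and the median was 0.57, 0.97 and -0.03 in litters A, B and C. Without the litter block the list did not pass once the control of litter A or B (0.186 and 0.163) or the knockout of litter B or C (0.106 and 0.0729) was left out. Its median was 0.291 without litter B (camera adjusted p = 0.0422), 0.769 without litter C, 0.264 with a pseudocount of 64 and 0.26 as deposited. Col5a2 and Sparc did not pass as deposited (adjusted p = 0.297 and 0.469) or without the litter block (0.218 and 0.23). The melanocyte shift was present in the same arrays as every gene group above, and the fibroblast shift, like that of the immediate-early genes, in litters A and B.

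Endothelial (12 measured, median 0.10, camera adjusted p = 0.653), leukocyte and Langerhans cell (19, 0.05, 0.193), skeletal muscle (15, 0.09, 0.193), adipocyte (8, 0.03, 0.854) and erythroid markers (6, -0.13, 0.357) did not shift as lists, and none of their members passed over all genes. As deposited the leukocyte and skeletal muscle lists were shifted up by the test (camera adjusted p = 0.0351 and 0.0154), with medians of -5.43e-05 and 0.09. With each array shifted to the same median they also passed (0.0383 and 0.0173). Adjusted over the list alone the endothelial Esam fell (-0.69 ± 0.12), from 14.7 ± 2.95 to 3.08 ± 1.75. The endothelial median was 0.06 as deposited. The leukocyte genes nearest to passing were H2-Ab1 (-0.74 ± 0.21), Cd74 (0.58 ± 0.17), Cd207 (0.37 ± 0.11) and Ptprc (0.28 ± 0.13), and the muscle genes Myl1 (0.31 ± 0.10), Myog (0.37 ± 0.14), Des (0.65 ± 0.27) and Acta1 (0.25 ± 0.17). Of the adipocyte genes Adipoq had a log2 change of 0.18 ± 0.12, and of the erythroid genes Hbb-b2 one of -0.37 ± 0.14 and Hba-a1 one of 0.15 ± 0.14. The adipocyte median and mean (-0.00668) differ in sign. With a litter or an array left out the lowest and highest values were -0.92 and -0.48 for H2-Ab1, 0.12 and 0.4 for Ptprc, 0.2 and 0.41 for Myl1, 0.35 and 1.04 for Des, -0.02 and 0.43 for Acta1, 0.04 and 0.28 for Adipoq, -0.6 and -0.22 for Hbb-b2 and -0.05 and 0.27 for Hba-a1.

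All 4 measured sex-linked genes changed. Xist, the RNA that coats the inactive X chromosome and is made in female cells, rose from 475.7 ± 77.1 in control pools to 1234.4 ± 22.4 in knockout pools (1.36 ± 0.10, adjusted p = 0.0196). The Y-linked Eif2s3y, Kdm5d and Uty had intensities of at least 43.4 in each control array and at most 4.62 in each knockout array. The list was lower (median -1.98, camera adjusted p = 0.00363; adjusted p = 0.465 with an estimated correlation; fry adjusted p = 0.0148). The median was -4.53 with a pseudocount of 1, -0.842 with 64 and -1.2 with the mean of each gene's probe sets. As deposited Xist did not pass (1.19, adjusted p = 0.177). The difference between the groups stands beside every comparison above, because all 3 litters had it.

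The litters were compared over all probe sets. Knockout minus control of litters A and B correlated across probe sets with r = 0.531, of A and C with r = 0.221 and of B and C with r = 0.263, and probe sets are not independent replicates. Among the 189 probe sets that passed, the median absolute log2 change was 1.15 in litter A, 1.21 in litter B and 0.989 in litter C.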

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

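Scaling each array to the same trimmed mean and leaving out genes of X and Y were chosen after seeing the data, and the other settings were planned. The 189 probe sets became 35 with the deposited scaling (29 of them among the 189), 699 with each array shifted to the same median (154 among them), 290 with a common trimmed mean (184), 1158 without the 40% dimmest probe sets (fewer tested), 6 without the trend, 477 with robust eBayes, 594 with a pseudocount of 1 and 59 with 64. They became 873 at an adjusted p of 0.10, 1739 at an unadjusted p under 0.05 with at least 1.5-fold change, and 0 by a plain paired test per probe set (4232 at an unadjusted p under 0.05). Leaving out a litter gave 0 to 2761. The fit without the litter block gave 135 (102 shared), and without the block and without 1 array it gave 12, 8 and 2431 (control of litters A, B and C left out) and 6, 4 and 15 (knockout left out). With 1 probe set per gene 222 passed, and without the genes known to lie on X or Y 165. Probe sets without a single named gene had no chromosome here and stayed in that fit. Apart from the inflammatory and hair follicle lists, the block changed no list call, and without it 16 of the 24 highest and lowest genes passed. Of those 24 genes 12 passed with the deposited scaling, 2 without the trend, 13 with a pseudocount of 64, 1 without litter A, 0 without litter B and 24 without litter C, and none changed sign in these settings. Gpx4 kept its direction and did not pass with the deposited scaling (-1.34, adjusted p = 0.122) or without the trend (-1.15, adjusted p = 0.1). It lay between -1.21 and -1.1 with a litter left out and did not pass without litter A or B. Without the block it had -1.2 and -1.12 without the control of litter A or B, and -1.1, -1.24 and -1.12 without the knockout of litter A, B or C, and passed in none of these 5. The adjusted p over all left-out arrays was 0.00165 to 0.276. The 14 lists became 0 with an estimated correlation, 9 without the block and the knockout of litter B, and 10 to 16 in the other settings. The correlations between litters were 0.655 (A and B), 0.29 (A and C) and 0.34 (B and C) over the 60% brightest probe sets. Some lists that had not passed turned in direction, by median or by test, in some settings. The antioxidant list had medians of -0.0828 (deposited), -0.022 (common median), -0.0239 (without litter C) and -0.0348 (no block, control of C left out), with no turn of its test. The ferroptosis list had medians of -0.158 (deposited), -0.097 (common median), -0.0133 (mean of probe sets), 0.0147 (without litter A), 0.000226 (without litter B) and, without the block, 0.0311 and 0.000131 (control of litter A or B left out) and 0.00248 and 0.022 (knockout of B or C). The heat shock list had -0.0945, -0.0338 and 0.103 in the first 3 of these settings, -0.0305 and 0.023 without litter A or B (0.196, not turned, without C) and, without the block, 0.00101 and 0.065 (control of A or B) and 0.0812 (knockout of B). The prostaglandin list had -0.0225 (common median), -0.0461 (dim probe sets left out), -0.00449 and -0.0438 (without litter A or C; -0.129, not turned, without B), -0.0183 (no block, control of C) and -0.000621 (no block, knockout of A). The differentiation list had 0.0845 without litter C and 0.0619 (no block, control of C), against -0.253, not turned, without litter A. The adipocyte list had -0.0508 (mean of probe sets), -0.0165 (without litter A; 0.0602, not turned, without B), 0.0204 (no block, control of C) and -0.0582 (no block, knockout of A). Its median alone turned to -0.00849 (deposited), -0.0144 (dim probe sets left out) and -0.0611 (pseudocount of 1), that of the leukocyte list to -5.43e-05 (deposited) and that of the skeletal muscle list to -0.0105 (without litter B). Hba-a1 was -0.05 without litter B (0.27, not turned, without C), and Acta1 -0.02 with no block and the control of C left out. The cause of these differences between settings was not tested. Testing fewer probe sets was not shown to be why 1158 passed without the dimmest.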

Other observations

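Genes outside the lists that passed the same test, are named here after their values were seen. The growth factor genes Epgn (412.8 ± 56.4 in controls, 769 ± 15.4 in knockouts, log2 change 0.88 ± 0.093, adjusted p = 0.0357), an EGF receptor ligand like Ereg, and Wnt7a (1.40 ± 0.13, adjusted p = 0.0243) rose, as did the TGF-beta receptor Tgfbr2 (0.95 ± 0.084, adjusted p = 0.0231) and the tissue factor gene F3 (686.2 ± 195.9 to 1857.5 ± 172.4, 1.45 ± 0.18, adjusted p = 0.0439). Among genes that fell were Tgfbi (1909.3 ± 1008.2 to 371.7 ± 66.5, -2.14 ± 0.25, adjusted p = 0.0379), the thioredoxin-binding Txnip (359.6 ± 28.9 to 161.8 ± 15.7, -1.08 ± 0.092, adjusted p = 0.0219) and its relative Arrdc3 (-1 ± 0.12), the cornified envelope genes Scel (-0.96 ± 0.11) and Tgm5 (-1.36 ± 0.14), the epidermal protease Klk5 (-1.19 ± 0.15), the vitamin D receptor Vdr (-0.86 ± 0.11) and the aryl hydrocarbon receptor Ahr (-0.76 ± 0.09). The microsomal glutathione transferase Mgst1 (-0.82 ± 0.097) and the NADPH-producing Idh1 (-0.93 ± 0.11) fell as well. Scel, Tgm5 and Klk5 do not stand for the differentiation genes as a whole, which moved in both directions, as given above. Of the genes in this paragraph Tgfbi alone passed with the intensities as deposited (-2.33, adjusted p = 0.0136). The values of Tgfbi and Vdr come from a probe set other than the gene's brightest, which did not pass, so Tgfbi is not among the 12 lowest.

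Of the tests below, those of the scaling in litter C and of the splits of the arrays were planned before their results were seen, and the others were chosen afterwards.

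All 3 knockout pools lacked the signal of Y-linked genes and had more Xist than the control pools of their litters, in which Xist was 38.5% of the knockout level. Fewer males among the knockout pups is a candidate explanation. All 5 measured genes that escape X inactivation were higher, with Eif2s3x at 0.57 ± 0.076 (adjusted p = 0.0507) and 0 of 5 past the threshold. Of the 5, Kdm5c (0.12 ± 0.11) and Kdm6a (0.07 ± 0.11) lay near 0. The 240 other expressed X-linked genes had a median log2 change 0.018 above that of 7980 autosomal genes. That median cannot decide, because X inactivation evens out their dose whether or not the pools differ in sex. Genes on X or Y were 6.67% (9 of 135) of the called genes with a chromosome, which argues against sex chromosome genes as the source of most calls. The 26 unnamed calls had no chromosome and are not in that count. Among them is the call with the smallest p of all. Its intensity was 277.1 ± 32.2 in controls and 2.69 ± 0.548 in knockouts, a pattern like that of the Y-linked genes. Autosomal genes that differ between the sexes cannot be told apart from the knockout here, because 0 knockout arrays had a Y signal above 16 and every control array did. Whether the knockout itself changes Y-linked RNA was not tested.

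The immediate-early genes had a median knockout difference of -0.10 in litter C, against 0.99 and 0.84 in litters A and B. Knockout cells in its control pool would lower Gpx4 there, but on the lower of the 2 probe sets it was 0.035 above the other controls, and scaling is argued against by a gap of at least 1.02 between litters A and B and litter C under the 3 other scalings. The litter C control, rather than its knockout, may be the array that stands apart: its distance from the other arrays of its group exceeded that of the knockout by 0.708 (0.811 against -0.103), and 21 of 24 genes were above both other controls. That control also lay above the other controls in the fibroblast list (1.02, against 0.216 for the knockout) and the differentiation list (0.844 against 0.0279), and its correlation with the knockouts (0.977 to 0.983) was near that with the other controls (0.975 and 0.978). Why that pool differs stays open, and no biological explanation was tested.

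Melanocyte markers were higher in all 3 litters. A lower share of keratinocytes and more melanocytes with unchanged expression cannot be told apart from a change within melanocytes. The mean log2 changes of 12 melanocyte and 10 fibroblast markers were 0.546 and 0.733 (two-sided permutation p = 0.35), but the 22 ran from -0.613 to 1.58, beyond their errors (chi-square sum against draws of t-distributed errors, p = 2e-05). The 12 melanocyte markers alone ran from 0.0755 to 1.11 (chi-square sum against the same kind of draws, p = 0.0031), which excludes neither, because signal from other cells or background, not measured here, lowers the rise of a marker. The lowest fibroblast value was a fall of -0.613, in Fn1. A lowered rise does not account for that fall, but whether the Fn1 signal came from fibroblasts was not measured. The permutation and the draws treat markers as independent, whereas the fibroblast list had an estimated correlation of 0.527. Their p-values do not measure the spread between litters. In litter C, a single pair of pools, the list medians were 0.503 for melanocyte and -0.0307 for fibroblast markers. An effect of Gpx4 loss in keratinocytes on melanocytes was not tested.

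The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: without the litter block the real split gave 135 calls, the highest other 1, and 1 of 10 splits gave as many. With the block, 1 of the 4 ways to exchange knockout and control within litters gave as many, with 189 real calls and 0 as the highest other, also too few.

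In litter C the interferon-stimulated genes were higher than in the other litters in both pools, by a median of 1.49 in the control and 1.22 in the knockout on the log2 scale.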
